A study of Mus musculus with 8 samples.

How the data were processed

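RNA levels were measured on Illumina bead arrays in female mouse pre-iPSCs (cells stalled partway through reprogramming, here derived from neural stem cells of a 129/MF1 background), which carried a reporter for Oct4 and grew in serum with LIF. Per the labels' protocols, the cells were stably transfected with PiggyBac vectors in which a CAG promoter drove the transgenes, selected with hygromycin, blasticidin or both, and taken at day 0. Total RNA was isolated with an RNeasy kit and converted to biotinylated cRNA with an Ambion MessageAmp kit. The 8 arrays fell into 4 groups of 2, namely empty vectors (EV), Nanog, Sin3a, and Nanog with Sin3a (Nanog+Sin3a). The labels number the arrays of a group as replicates and do not say whether these came from separate cultures, so the p-values measure only the spread between arrays.

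The deposited values are intensity per probe from the GenomeStudio software, per the submitters' processing notes, which give neither a version nor settings. The units were checked on the values themselves, which held 45281 probes per array. They ran from -24 to 14965 on a linear scale, with 47.3% to 47.7% of values below 0, so a background had been subtracted. The sorted values of 7 arrays differed by at most 0.618% above an intensity of 16, so the authors' values were taken as already quantile-normalised between arrays. For the second Sin3a array that difference was 4.14%. For arrays, the number of arrays per group limits the precision of each value.

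The values were kept as deposited, raised to 16 where lower (4 on the log2 scale, called the floor) and converted to log2. The array annotation gave 1 symbol for 34885 probes, several for 18 and none for 10378, over 19057 symbols. Gene identifiers of 34807 probes were looked up in a RefSeq gene table, and this changed 0 symbols. Each symbol was represented by its probe of highest mean value, and probes with no symbol or several were kept as unnamed features. Features above their array's median in at least 2 arrays were tested, which left 13604 features, 10430 of them with a symbol. That median was the floor on every array, so these were features above the floor in at least 2 arrays.

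Differences were tested in R 4.3.3 with limma 3.58.1, as lmFit and eBayes with an intensity trend on a fit with 1 coefficient per group. The fit had 4 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. All tests were two-sided. There were 5 comparisons between pairs of groups, the interaction (the Sin3a effect with Nanog minus the Sin3a effect without it), and 1 main effect for each transgene. The comparisons, the floor, the filter, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

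The second Sin3a array proved far noisier than the others at low and middle intensities. Every comparison was therefore also fitted without that array (7 arrays, 12987 features, 10086 with a symbol, 3 residual degrees of freedom), and with all 8 arrays on the 2300 features whose mean log2 value was above 9, an intensity of 512, called bright features. A fit without both arrays of the Sin3a group was also made. These 3 fits were chosen after the data had been seen. In any fit where a group kept 1 array, that array was assumed to vary like those of the other groups.

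The rule for named genes took Nanog and Sin3a everywhere. In each comparison it added up to 10 named genes with the largest rise and 10 with the largest fall among those that passed the test and whose arrays did not overlap between the groups compared. For each gene list it took up to 4 members with the largest change among those that passed, or up to 2 given as values where none did. A fold change against a group at the floor was given as a lower bound.

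The 31 gene lists covered pluripotency factors, neural stem cells, neurons, the Sin3 complex, the NuRD complex, DNA methylation, mesenchymal cells, epithelial cells, primitive endoderm, trophectoderm, mesoderm and primitive streak, ERK targets, Wnt targets, LIF and Stat3 targets, p53 targets, G2/M, G1/S, CDK inhibitors, germline genes, the 2-cell-like state, X inactivation, imprinted genes, the interferon response, the integrated stress response, heat shock, glycolysis and hypoxia, cholesterol synthesis, myeloid and blood cells, endothelium, astrocytes and oligodendrocytes, and housekeeping genes. The 27 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it.

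The procedure was tested on simulated data in which 100 genes were changed by 1 and 100 by 2 on the log2 scale in the Nanog against EV comparison. These genes were drawn only from features well above the floor in EV, so the recovery does not describe features near the floor. The EV, Nanog and Nanog+Sin3a arrays were drawn with the spread of the 7-array fit, and the real Sin3a arrays were kept. With both Sin3a arrays in the fit, 28% and 57% of these changes were recovered, with 1 false call among 86. Without the second Sin3a array, 76% and 100% were recovered, with 5 false calls among 181. Correlations between effects that share the EV arrays were set beside 50 simulations of unchanged groups. Alternatives covered the floor, the scaling between arrays, the filter, the choice of probe, a replicate block, the variance model, a minimum change, the arrays in the fit and the omission of each array in turn. Median centring used the medians of all probes that passed the main filter, also where only bright features were tested. Later days of reprogramming were not analysed here.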

Results

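RNA levels were compared at day 0 between pre-iPSCs with empty vectors (EV), Nanog, Sin3a, or both transgenes (Nanog+Sin3a), with 2 arrays per group and 8 in all. Nanog is a homeodomain transcription factor of the pluripotency network, and Sin3a is the scaffold of a co-repressor complex that carries histone deacetylases. The series title asks whether that complex and Nanog cooperate in reprogramming. On each array 16157 to 16365 of 45281 probes, or 35.7% to 36.1%, lay above the floor of 16 intensity units. Across the 13604 tested features on the log2 scale, the arrays of a group correlated at r = 0.994 for EV and 0.988 for Nanog. The values were 0.985 for Nanog+Sin3a and 0.802 for Sin3a. These correlations are across features, which are not independent replicates.

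The second Sin3a array stood apart from the other 7. Among the 7740 probes with a mean log2 value from 5 to 8, 78.8% differed by over 1 (log2) from the first Sin3a array, against 0.271% between the EV arrays. Among the 2684 probes at 9 or above, 0.224% did so. The first principal component held 79.8% of the variance of the 8 arrays and placed this array at 161 and the others between -24.8 and -20.9. Without it, the first component held 46.9% and placed the 4 arrays with the Nanog transgene between -24.3 and -9.12 and the 2 EV arrays and the first Sin3a array between 22.8 and 28.4. In the comparisons, values from 7 arrays are from the fit without the second Sin3a array, and bright features are those with a mean log2 value above 9 over all 8 arrays.

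**Figure D1:**
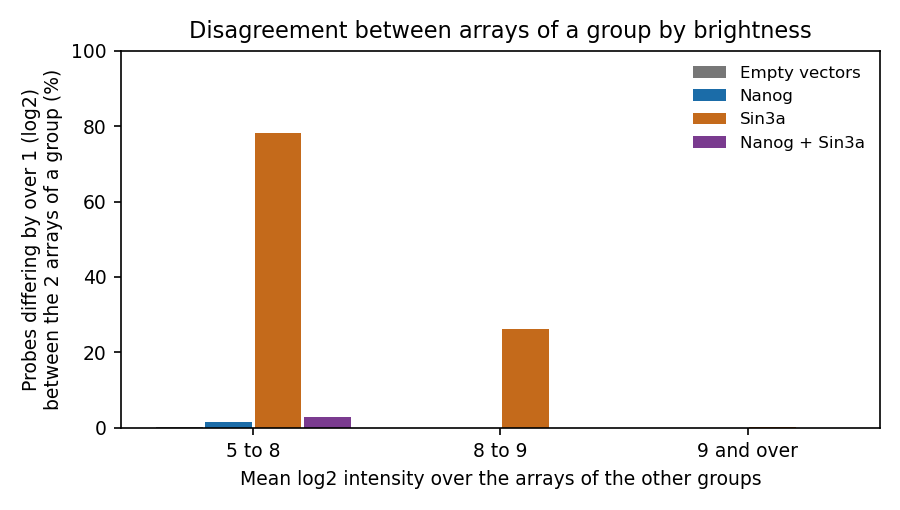
Share of probes, in percent, that differed by over 1 (log2) between the 2 arrays of each group, by the mean log2 value of the probe over the arrays of the other groups (5 to 8, 8 to 9, and 9 or above). The Sin3a arrays differed at 78.2% of probes in the lowest class and 0.223% in the highest, and the other groups at no more than 2.85% in any class.

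Both transgenes were seen as RNA. The Nanog probe read an intensity of 425 ± 85.6 (SD, n = 2) with Nanog and 287 ± 3.04 with Nanog+Sin3a, against -4.50 ± 1.27 with EV and -9.75 ± 3.46 with Sin3a. This was at least 26.3-fold above EV with Nanog (log2 4.72, SE 0.18, adjusted p = 0.00107 in 7 arrays) and at least 18.0-fold with both transgenes (log2 4.17, SE 0.18, adjusted p = 0.000640). The Nanog+Sin3a and Nanog groups differed by -0.55 (SE 0.18) in this probe, which did not pass the test (adjusted p = 0.344 in 7 arrays). Another Nanog probe stayed between -4.80 and 21.0 on all 8 arrays. The Sin3a probe read 296 ± 47.7 with EV, 408 ± 90.6 with Nanog, 1162 ± 28.6 with Sin3a and 1484 ± 0.990 with both transgenes. In 8 arrays Sin3a rose 5.05-fold with both transgenes against EV (log2 2.34, SE 0.18, adjusted p = 0.0130), and it was 3.96-fold higher with Sin3a alone (log2 1.98, SE 0.18), where the test was not passed over all features (adjusted p = 0.0837) but was over the bright features (1.06e-07). With 8 arrays, the Nanog probe gave adjusted p = 0.0659 for Nanog against EV and 0.0344 for Nanog+Sin3a against EV. The second of these exceeded 0.05 without any 1 of the Nanog, Nanog+Sin3a or EV arrays, at 0.119 without either Nanog array, 0.271 and 0.266 without the first and second Nanog+Sin3a array, and 0.185 and 0.299 without the first and second EV array. The Sin3a probe's value for Nanog+Sin3a against EV did so without the first (0.129) or second (0.0901) Nanog+Sin3a array and without the first (0.0733) or second (0.130) EV array.

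**Figure D2:**
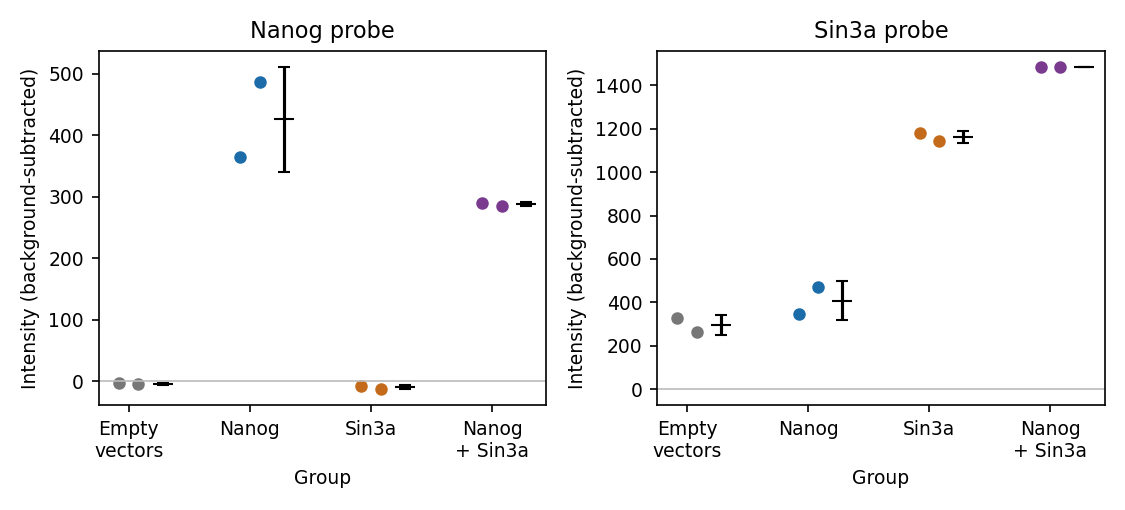
Background-subtracted intensity of the Nanog probe and of the Sin3a probe on each of the 8 arrays (points), with the mean and SD of the 2 arrays of each group. The Nanog probe lies between 285 and 486 in the arrays with the Nanog transgene and below 0 in the others, and the Sin3a probe lies at 1142 or higher in the arrays with the Sin3a transgene and at 473 or lower in the others.

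Nanog against EV asks what Nanog alone changed in these cells. In 7 arrays Evx1, a homeobox gene of the primitive streak, rose 12.9-fold (log2 3.69, SE 0.16, adjusted p = 0.00117, n = 2 against 2), and Palmd, which encodes palmdelphin, rose 6.62-fold (log2 2.73, SE 0.20). Wnt5a, a ligand of non-canonical Wnt signalling, rose at least 4.96-fold (log2 2.31, SE 0.20, 0.57 in another probe), and Ghr, the growth hormone receptor, rose 5.15-fold (log2 2.36, SE 0.19, 0.72 in another probe). The other genes with the largest rises were Them5 (log2 3.16, 0.93 in another probe), Nptx2 (3.09), Sprr2d (3.08), Haao (2.59, 1.44 in another probe) and Slco2a1 (2.38, other probes 1.03 and 1.24), with Them5, Nptx2 and Sprr2d at the floor in EV. Il13ra1, a receptor subunit for interleukin-13, fell (log2 -2.19, SE 0.15, adjusted p = 0.00409), as did Tpt1 (-2.10, SE 0.31), the translationally controlled tumour protein, and Prxl2a (-1.99, SE 0.16), a peroxiredoxin-like gene. Ptx3 (-2.45), A230083G16Rik (-2.42), Asic1 (-2.08) and 1700009N14Rik (-1.88) fell to the floor, and Rap1gap (-2.12, 0.00 in another probe), Eif4e3 (-1.91) and Crym (-1.82) fell too.

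In all, 350 of 12987 features changed with Nanog in 7 arrays, 185 up and 165 down, among them 163 named genes up and 95 down. With all 8 arrays limma called 0 (1054 at an unadjusted p under 0.05), and on the bright features it called 222, 105 up and 117 down. The 7-array count became 0 without the first Nanog array, 1 without the second, 95 and 37 without the first and second Nanog+Sin3a array, and 0 without either EV array. For bright features the count was 489 and 92 without the first and second Nanog array and 69 and 28 without the first and second EV array.

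Of the 15 measured pluripotency factors, 3 rose with Nanog, 0 fell and 12 did not pass (4 up and 1 down adjusted over the list alone). They were Nanog itself, which is the transgene, Gbx2 (log2 1.33 from the floor, SE 0.24, adjusted p = 0.0444), a homeobox gene downstream of LIF, and Gdf3 (0.91, SE 0.12, 0.0176), a TGF-beta family ligand. Pou5f1, looked at after the values were seen, was at a mean log2 value of 10.11 ± 0.11 (SD, n = 2) in EV and differed by -0.12 with Nanog (adjusted p = 0.643). Of 14 mesenchymal genes, 2 rose, 1 fell and 11 did not pass (6 up and 2 down adjusted over the list alone), with Thy1, a surface glycoprotein, at 1.13 (SE 0.12, adjusted p = 0.0103), Sparc, a matrix protein, at 0.66 and Tgfbi at -0.57 (adjusted p = 0.0453). Of 15 genes of the integrated stress response, 2 fell and 13 did not pass (2 up and 6 down adjusted over the list alone), with Trib3 at -0.98 and Chac1 at -0.88. Of 16 genes of glycolysis and hypoxia, 2 fell and 14 did not pass (0 up and 2 down adjusted over the list alone), with Ankrd37 at -0.93 and Pgk1, the phosphoglycerate kinase, at -0.59.

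Among the lists with 1 call, Egfr fell (-0.66, 1 of 6 neural stem cell genes), as did Tfap2a (-0.76, 1 of 8 trophectoderm genes) and Pgk1 (1 of 10 housekeeping genes). Gbx2 rose (1 of 13 LIF and Stat3 targets), as did Rhox5 (1.11, 1 of 4 germline genes), Grb10 (0.81, 1 of 9 imprinted genes) and Flt1, a VEGF receptor (0.79, 1 of 5 endothelial genes). Adjusted over the list alone, these lists had 2 up and 2 down (neural stem cells), 0 and 1 (trophectoderm), 1 and 1 (housekeeping), 2 and 1 (LIF and Stat3), 1 and 0 (germline), 2 and 1 (imprinted), and 2 and 1 (endothelium). No member passed in the lists of neurons (7 measured), the Sin3 complex (16), the NuRD complex (8), DNA methylation (5), epithelial cells (8), primitive endoderm (7), ERK targets (14), p53 targets (12), G2/M (15), G1/S (18), CDK inhibitors (7), the 2-cell-like state (5), the interferon response (8), heat shock (10), cholesterol synthesis (13), or astrocytes and oligodendrocytes (4). Of these, adjusted over the list alone, ERK targets had 3 up, epithelial cells 3 down, neurons, DNA methylation, p53 targets and CDK inhibitors 1 up each, and primitive endoderm and cholesterol synthesis 1 down each. Camera called 0 of 27 lists in 7 arrays (smallest adjusted p = 0.0771) and 0 in 8 arrays. Fry, which tests whether a list's genes move on balance 1 way, called 4 up in 7 arrays, namely pluripotency (0.0204), mesenchymal cells (0.0373), ERK targets (0.0152) and endothelium (0.0373), and in 8 arrays pluripotency (0.00475) and CDK inhibitors (0.0424). Without Nanog, which is the transgene, fry did not call the pluripotency list (adjusted p = 0.107 in 7 arrays and 0.173 in 8). The lists of mesoderm and primitive streak, Wnt targets, X inactivation, and myeloid and blood cells had 1, 2, 2 and 1 measured members and were not tested.

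Nanog+Sin3a against EV asks what both transgenes changed together. In 8 arrays Cbr3, a carbonyl reductase, rose 4.96-fold (log2 2.31, SE 0.12, adjusted p = 0.00404, n = 2 against 2). Krt14, a basal epithelial keratin, rose 3.04-fold (log2 1.60, SE 0.12, adjusted p = 0.0130), Homer2, a synaptic scaffold gene, rose 6.35-fold (log2 2.67, SE 0.32, 0.0392), and Arhgdib rose 3.19-fold (log2 1.68, SE 0.16, 0.0241). Popdc3 (log2 1.94), Tuft1 (1.34), Prnp (1.18), the prion protein, and Prelp (1.17) also rose. Upp1, which cleaves uridine, fell (log2 -1.63, SE 0.12, adjusted p = 0.0130), as did Slc7a3, a carrier of cationic amino acids (-1.76, SE 0.14, 0.0130), though another probe of Slc7a3 gave 0.64. Prxl2a (-2.09), Pgk1 (-0.85, other probes -1.83 to 0.26), Pa2g4 (-0.74), Rpa3 (-0.73), Ubxn1 (-0.66) and Timp1 (-0.59) fell as well. So did A230083G16Rik (-2.42, to the floor) and Cpn1, whose 2 other probes gave -1.13 and -0.03.

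In 7 arrays the alpha-class glutathione S-transferases rose, Gsta2 at least 14.5-fold (log2 3.86, SE 0.17, adjusted p = 0.000640) and Gsta1 13.4-fold (log2 3.74, SE 0.19, 0.00105). Gsta2, Igfbp6 and Nptx2 were at the floor in EV, so their changes are lower bounds and cannot be ranked. Evx1 rose 11.6-fold (log2 3.53, SE 0.16), Palmd 9.90-fold (log2 3.31, SE 0.20) and Igfbp6, which binds insulin-like growth factors, at least 6.79-fold (log2 2.76, SE 0.18). Nptx2 (log2 2.73, from the floor), Slco2a1 (2.71, other probes 1.00 and 1.87), Ank (2.67) and Homer2 (2.67) rose too. Il13ra1 fell (log2 -2.37, SE 0.15, adjusted p = 0.00204), as did Cd24a, a surface glycoprotein (-2.35, SE 0.36, 0.0184), and Slc25a4, the mitochondrial carrier of ADP and ATP (-2.39, SE 0.53, 0.0481). Ltbp1 (-2.59, 0.74 in another probe), Ptx3 (-2.45, to the floor), Tpt1 (-2.41), Syne4 (-2.18) and Rap1gap (-2.14, 0.37 in another probe) fell too.

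**Figure D3:**
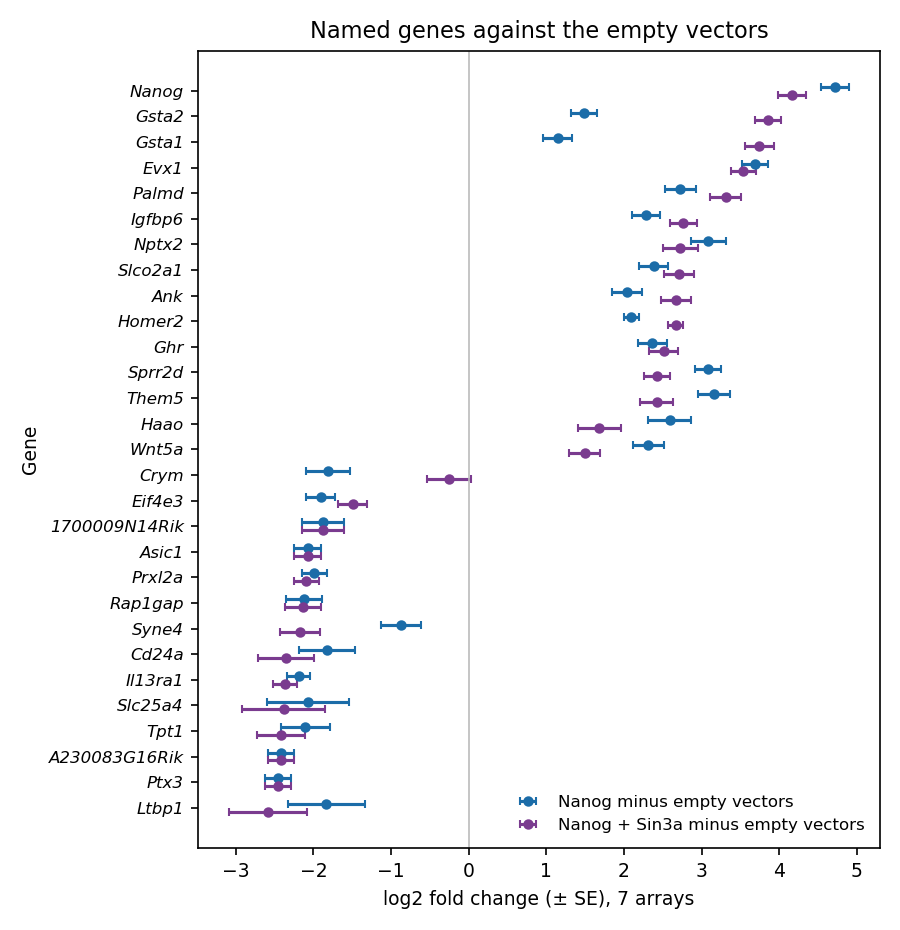
Log2 fold change against EV in 7 arrays, with standard errors, of the genes named by the rule, for Nanog (n = 2) and for Nanog+Sin3a (n = 2). Evx1 was at 3.69 with Nanog and 3.53 with both transgenes, and Gsta2, at the floor in EV, was at 1.48 or more and 3.86 or more.

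The 8-array fit called 35 features for both transgenes against EV, 21 up and 14 down, with 20 named genes up and 11 down. The split was 4 up and 0 down with median centring, and 186 up and 206 down among the 392 called on the bright features. In 7 arrays 950 changed, 484 up and 466 down, with 428 named genes up and 312 down, and they included all 35. The count of 35 became 6 without either Nanog array, 0 without either Nanog+Sin3a or EV array, 863 without the first Sin3a array and 950 without the second, and the count of 950 became 380 and 603 without the first and second Nanog array, 5 and 0 without the first and second Nanog+Sin3a array, and 0 without either EV array. Among bright features it was 204 and 196 without the first and second Nanog+Sin3a array and 90 without the second EV array.

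By list, in 7 arrays, 3 of 15 pluripotency factors rose with both transgenes, 1 fell and 11 did not pass (3 up and 1 down adjusted over the list alone). Besides Nanog, Gbx2 was at 1.47 (at the floor in EV), Gdf3 at 0.54, and Sall4, a zinc finger factor of embryonic stem cells, at -1.37 (SE 0.16, adjusted p = 0.00854). Of 14 mesenchymal genes 5 rose, 1 fell and 8 did not pass (5 up and 1 down adjusted over the list alone), among them Dcn, the proteoglycan decorin, at 2.42 (SE 0.34, adjusted p = 0.0153, at the floor in EV), Tgfbi at -1.06 and Thy1 at 0.75. Of 15 genes of the integrated stress response 1 rose, 4 fell and 10 did not pass (2 up and 6 down adjusted over the list alone), with Slc7a11, the cystine carrier, at 0.91, Trib3 at -0.74, Cebpb at -0.73 and Chac1 at -0.66. Of 5 endothelial genes 2 rose, 1 fell and 2 did not pass (2 up and 1 down adjusted over the list alone), with Flt1 at 1.49 (SE 0.10, adjusted p = 0.00226), Tek, the angiopoietin receptor, at 1.22 and Esam at -1.08. Of 13 LIF and Stat3 targets 1 rose, 2 fell and 10 did not pass (2 up and 3 down adjusted over the list alone), with Gbx2, Bcl3 at -1.12 and Socs3 at -0.91. Of 6 neural stem cell genes 2 fell and 4 did not pass (1 up and 3 down adjusted over the list alone), with Nes, the intermediate filament nestin, at -0.78 and Egfr at -0.73. Of 10 heat shock genes 2 fell and 8 did not pass (0 up and 2 down adjusted over the list alone), with Hspe1 at -0.71 and Hsp90aa1 at -0.60.

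In several lists 1 member rose, 1 fell and the rest did not pass, namely glycolysis and hypoxia (16 measured, Pfkp 0.78 and Pgk1 -0.85), primitive endoderm (7, Srgn 0.84 and Dab2 -0.83) and G2/M (15, Cdc20 0.42 and Bub1b -0.52). A single member rose among neurons (Ncam1, 1.34, of 7), the Sin3 complex (Sin3a itself, of 16), p53 targets (Phlda3, 0.90, of 12), CDK inhibitors (Cdkn2c, 0.81, of 7), germline genes (Rhox5, 1.45, of 4) and imprinted genes (Grb10, 1.19, of 9). A single member fell among G1/S genes (Pcna, the replication clamp, -1.19, of 18), cholesterol synthesis (Idi1, -1.21, of 13), ERK targets (Egr2, -0.87, of 14), trophectoderm (Tfap2a, -0.64, of 8) and housekeeping genes (Pgk1, of 10). No member passed in the NuRD complex (8 measured, Mta2 -0.64 and Chd3 -0.62), DNA methylation (5, Dnmt3b 0.29 and Tdg -0.23), epithelial cells (8, Cldn3 -0.82 and Pkp3 -0.67, to the floor), the 2-cell-like state (5, Tcstv3 0.83 and Gm428 0.72, from the floor), the interferon response (8, Ddx58 -0.69 and Stat2 0.51, from the floor), or astrocytes and oligodendrocytes (4, Cnp 0.31 and Mobp 0.23, from the floor). Adjusted over the list alone, these counts were the same except for 2 up in the 2-cell-like state, 1 down in the interferon response, 3 up and 2 down in p53 targets, 2 up in glycolysis and hypoxia, 1 up in trophectoderm and in cholesterol synthesis, and 1 down in CDK inhibitors and in germline genes. Camera called 0 of 27 lists (smallest adjusted p = 0.313 in 7 arrays), and fry called pluripotency (0.0331) and endothelium (0.0218) up in 7 arrays and pluripotency (0.0118) in 8. The pluripotency list without Nanog was not called (0.654 in 7 arrays and 0.490 in 8).

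Sin3a against EV asks what Sin3a alone changed. On the bright features of all 8 arrays, 4 genes rose and 0 fell, and all were chosen after their values were seen except Sin3a itself (log2 1.98, SE 0.15, n = 2 against 2). Acta2, the smooth muscle actin, rose 1.02 on the log2 scale (SE 0.15, adjusted p = 0.00101), from a mean of 8.78 ± 0.15 (SD) to 9.81 ± 0.10. Cbr3 rose by 0.68 (SE 0.13, adjusted p = 0.0387) and Ckb, the brain creatine kinase, by 0.62 (SE 0.12, 0.0336). Sin3a passed in each of the 8 fits of the bright features that left out 1 array. Acta2 did not pass without the second EV array (adjusted p = 0.187). Cbr3 did not pass without either Nanog+Sin3a array (0.0989 and 0.0958), either EV array (0.258 and 0.674) or the second Sin3a array (0.277). Ckb did not pass without either Nanog+Sin3a array (0.0630 and 0.0621), the second EV array (0.951) or either Sin3a array (0.138 and 0.312). The count of 4 became 13 (9 up and 4 down) and 16 (10 and 6) without the first and second Nanog array, 2 without either Nanog+Sin3a array, 1 without the second EV array and 10 without the first Sin3a array, 3 of them up and 7 down. With median centring, by the medians of all filtered probes and not of the bright features, Sin3a was the 1 bright feature called.

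Over all features limma called 0 for Sin3a against EV in 8 arrays (404 at an unadjusted p under 0.05, smallest adjusted p = 0.0837) and 0 in 7 (518). The first of these became 6774 without the first Sin3a array, which left the noisier array to stand for the group. The median of all features was -0.10 in 8 arrays and 0.64 with median centring, so changes in that fit are relative to this shift. Of the lists, 16 genes of glycolysis and hypoxia were called down by camera in 8 arrays (median -0.30, adjusted p = 0.0327, 0 members passed) but not with an estimated correlation (adjusted p = 0.917 with an estimated correlation). In 7 arrays that list was also called down (median -0.18, adjusted p = 0.00596), with Ankrd37 at -0.63 and Ndrg1 at -0.48, neither of which passed. Pluripotency factors were called up (median 0.24, adjusted p = 0.0495), with Sox2 at 1.41 (at the floor in EV) and Klf5 at 0.69, and so were mesenchymal genes (median 0.17, adjusted p = 0.0308), with Acta2 at 0.95 and Ccn2 at 0.82. In each of these 3 lists 0 members passed over all features, and 0, 2 and 2 were up adjusted over the list alone. All 3 calls were lost with an estimated correlation (adjusted p = 0.517 with an estimated correlation), and they rest on 1 Sin3a array.

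Nanog+Sin3a against Nanog asks what Sin3a added to Nanog, the cooperation named in the title. In 7 arrays Gsta1 rose 6.04-fold (log2 2.59, SE 0.19, adjusted p = 0.0317, n = 2 against 2; its 2 other probes gave 1.83 and 2.64) and Gsta2 rose 5.18-fold (log2 2.37, SE 0.17, 0.0317). On the bright features of all 8 arrays 5 genes rose, and all but Sin3a (log2 1.88, SE 0.15, adjusted p = 2.73e-07) were chosen after their values were seen. Krt14 rose by 1.30 (SE 0.13, adjusted p = 2.96e-06), from a mean log2 value of 9.32 ± 0.15 (SD) with Nanog to 10.62 ± 0.10 with both transgenes, and Cbr3 rose 1.00 (SE 0.13, 0.000284). Pqlc3 rose by 0.82 (SE 0.13, 0.00203), Sgk1, a kinase induced by serum and glucocorticoids, rose by 0.72 (SE 0.11), and 1 unnamed feature fell (-0.69). Sin3a and Krt14 passed whichever array was left out. Cbr3 (adjusted p = 0.0579) and Sgk1 (0.0721) did not pass without the second Nanog+Sin3a array, nor Pqlc3 without the first (0.0591) or second (0.0721), and the unnamed feature passed in 3 of 8 such fits.

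Over all features 2 of 12987 changed in 7 arrays (1434 at an unadjusted p under 0.05), and these were Gsta1 and Gsta2. That count became 0 without any further array, whichever of the 6 was tested, and 0 with the replicate number as a block. With 8 arrays limma called 0 (546 at an unadjusted p under 0.05), 1 without the first Sin3a array and 2 without the second. On the bright features the 6 calls became 63 and 16 without the first and second Nanog array and 2 without the second Nanog+Sin3a array, and median centring called 0 (2 at an unadjusted p under 0.05). Camera called 0 of 27 lists in 7 arrays (smallest adjusted p = 0.0672, for ERK targets), and 0 in 8. Fry called ERK targets down in 7 arrays (0.00741) and CDK inhibitors down in 8 (0.0316).

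Nanog+Sin3a against Sin3a asks what Nanog added to Sin3a. In 8 arrays Arhgdib rose 3.38-fold (log2 1.76, SE 0.16, adjusted p = 0.0292, n = 2 against 2) and Cbr3 3.11-fold (log2 1.63, SE 0.12, 0.0178). Nanog (4.17, from the floor), Tuft1 (1.29), Prnp (1.01), Spop (0.82), Fkbp4 (0.77), Ndufa9 (0.61) and Atp2a3 (0.58) also rose, though Ndufa9 and Atp2a3 were at -0.13 and -0.16 with median centring. Prxl2a fell (log2 -2.40, SE 0.18, adjusted p = 0.0178, -1.04 in another probe), as did Axl, a receptor tyrosine kinase (-1.15, SE 0.12, 0.0322), and Aldh3a1, an aldehyde dehydrogenase (-1.15, SE 0.14, 0.0492). Upp1 (-1.63), Slc7a3 (-1.63, 0.81 in another probe), Psat1 of serine synthesis (-0.74) and Pgk1 (-0.74, other probes -0.91 and 1.23) fell too.

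In 7 arrays, where 1 Sin3a array stood for the group, Gsta2 rose 11.9-fold (log2 3.57, SE 0.20), Gsta1 9.48-fold (log2 3.25, SE 0.23) and Evx1 9.40-fold (log2 3.23, SE 0.20, adjusted p = 0.00420). Igfbp6 rose at least 6.79-fold, Anxa8 6.73-fold and Fam20a at least 5.47-fold, and Nptx2 (log2 2.73, from the floor), Pid1 (2.67) and Palmd (2.59) rose as well. Sox21, a Sox factor of neural progenitors, fell (log2 -2.71, SE 0.28, adjusted p = 0.0155, -0.91 in another probe), as did Krt20 (-2.32), Prxl2a (-2.45) and Stk32a (-2.18, -0.29 in another probe). Ptx3 (-3.08), Mfng (-2.50, -0.34 in another probe) and Samd5 (-2.21) fell to the floor. Tpt1 (-2.46), Spink10 (-2.26) and Syne4 (-2.10) fell in this fit but were at 0.12, 0.12 and 0.31 without the first Sin3a array. Among list members, Rhox5 rose (2.12, SE 0.14, adjusted p = 0.00497), as did Dcn (2.42, from the floor), Grb10 (1.40), Tek (1.36) and Phlda3 (0.96), while Sall4 (-1.65), Sox2 (-1.35), Cebpb (-1.03), Socs3 (-0.95) and Egfr (-0.85) fell.

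The 8-array fit called 20 features for Nanog+Sin3a against Sin3a, 11 up and 9 down, and 19 of them were also called in 7 arrays, where 251 changed (141 up and 110 down). The median of all features was 0.12 in 8 arrays and -0.62 with median centring, which called 0 (limma called 1574 at an unadjusted p under 0.05 as reported), and cyclic loess called 0 up and 1 down. The count of 20 became 0 without any 1 of the Nanog, Nanog+Sin3a or EV arrays, 7019 without the first Sin3a array and 251 without the second, and the count of 251 became 0 without any further array, whichever of the 6 was tested. Of the bright features 266 changed, 129 up and 137 down, and this count was 451 and 460 without the first and second Nanog array, 106 and 149 without the first and second Nanog+Sin3a array, and 82 without the second Sin3a array. Camera called 0 of 27 lists (smallest adjusted p = 0.648 in 7 arrays).

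The interaction asks whether both transgenes together differed from the sum of their separate log2 effects. Acta2, chosen after its values were seen, was the 1 bright feature called, at -1.54 (SE 0.21, adjusted p = 0.000863). Its mean log2 value was 8.78 ± 0.15 (SD, n = 2) with EV, 9.48 ± 0.01 with Nanog, 9.81 ± 0.10 with Sin3a and 8.97 ± 0.25 with both transgenes. Over all features Acta2 had an adjusted p of 0.752 in 8 arrays and 0.535 in 7, and on the bright features it was 0.0571 without the second EV array (log2 -1.43, SE 0.23) and 0.621 with median centring (-2.28, SE 0.83). For Sin3a the interaction was -0.10 (SE 0.25, adjusted p = 0.864), and in 7 arrays it was 2.10 for Gsta1 and at most 2.09 for Gsta2, which was at the floor in EV (both adjusted p = 0.479).

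Over all features limma called 0 for the interaction in 8 arrays (389 at an unadjusted p under 0.05) and 0 in 7 (733), and 5975 in the 8-array fit without the first Sin3a array. Without the second EV array 0 bright features were called, 17 without the first Nanog array, 4 without the second, 2 without the first EV array and 3 without the second Sin3a array. By camera in 7 arrays, pluripotency factors (median -0.31, adjusted p = 0.00204), ERK targets (-0.18, 0.00853) and mesenchymal genes (-0.24, 0.0397) had a lower value than the sum, and genes of glycolysis and hypoxia a higher one (0.25, 0.00264). The members with the largest values were Sox2 (-1.35, at the floor in EV and Nanog), Klf5 (-1.18), Egr2 (-0.76), Etv5 (-0.60), Dcn (1.84, at the floor in EV and Sin3a), Acta2 (-1.46), Ankrd37 (1.12) and Ndrg1 (0.96), and 0 members passed. Adjusted over the list alone, 3 pluripotency factors were below 0 and 3 genes of glycolysis and hypoxia above it. None of the 4 calls held with an estimated correlation (adjusted p = 0.352 with an estimated correlation for pluripotency, ERK targets and glycolysis, and 0.412 for mesenchymal genes). In 8 arrays glycolysis and hypoxia was called up (median 0.50, adjusted p = 0.0128, and adjusted p = 0.585 with an estimated correlation). The median of all features was 0.13 in 8 arrays and -0.61 with median centring.

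Over both backgrounds, the Nanog main effect (4 arrays against 4, or 4 against 3 in 7 arrays) called 140 features in 8 arrays, 72 up and 68 down, and 1041 in 7 arrays, 504 up and 537 down. Nanog itself was at 4.44 or more (adjusted p = 0.00832 in 8 arrays). With median centring the split was 15 up and 8 down, with all features at a median of -0.29 against 0.08 as reported. The count of 140 became 54 and 7 without the first and second Nanog array, 8 and 12 without the first and second Nanog+Sin3a array, 32 and 17 without the first and second EV array, 6768 without the first Sin3a array and 1041 without the second. The Sin3a main effect called 1 feature in 8 arrays, Sin3a itself (1.93, adjusted p = 0.0199), and 0 in 7 arrays (970 at an unadjusted p under 0.05). That 1 call remained at a count of 1 without the second Nanog array and became 0 without the first Nanog array, either Nanog+Sin3a array, either EV array or the second Sin3a array, and 6184 without the first. The median of all features was -0.06 for this effect and 0.31 with median centring. On the bright features 8 were called for the Sin3a main effect, 5 up (Sin3a, Krt14 0.96, Cbr3 0.84, Sgk1 0.62, Pqlc3 0.54) and 3 down (Fads1 -0.40, Dazap2 -0.38 and 1 unnamed at -0.48), and all but Sin3a were chosen after their values were seen. Sin3a, Krt14, Cbr3 and Sgk1 passed in each of 8 fits with 1 array left out, and Pqlc3 in 4, Fads1 in 3, Dazap2 in 2 and the unnamed feature in 3. The count of 8 became 47 and 30 without the first and second Nanog array, 5 and 4 without the first and second Nanog+Sin3a array, 4 without the second EV array, and 1 with median centring.

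The effect of Nanog without Sin3a and its effect with Sin3a, which share no array, correlated across features at Pearson's r = 0.620 in 7 arrays and 0.289 in 8. The Sin3a effects without and with Nanog correlated at 0.0969 in 7 arrays and 0.0454 in 8. Effects against EV share the EV arrays, which raises their correlation. In 7 arrays the Nanog and Nanog+Sin3a effects against EV correlated at 0.758 (covariance 0.144), where simulated unchanged groups gave 0.501 (0.0227). In 8 arrays the values were 0.755 (0.136) against 0.501 (0.146). Every 8-array simulation gave all groups the spread of that fit, which the second Sin3a array raised. Its covariances are therefore no fair reference, since the arrays of the other groups were less noisy. With 1 EV array for each effect, a comparison added after the data were seen, the Nanog and Nanog+Sin3a effects correlated at 0.604 and 0.644 in 7 arrays and 0.601 and 0.642 in 8. For Nanog with Sin3a the values were 0.269 (0.0277) against 0.410 (0.0227) in the simulations, and for Sin3a with Nanog+Sin3a 0.297 (0.0353) against 0.410 (0.0228). In 8 arrays these pairs gave 0.126 and 0.139, with covariances of 0.0389 against a simulated 0.147 and 0.0498 against 0.146. With 1 EV array for each effect in 7 arrays they gave 0.101 and 0.0992, and 0.119 and 0.167. All comparisons of a fit share 1 variance estimate per feature, which raises the overlap of their calls. Expected counts of shared calls assume independent calls and are therefore too low, by an amount that was not computed. Of the 350 features called with Nanog and the 950 called with both transgenes against EV, 307 were shared in the same direction, 161 up and 146 down, which the shared EV arrays raise by an amount that was not computed. Between Nanog against EV and Nanog+Sin3a against Sin3a, which share no array, 154 called features were shared in the same direction, 89 up (2.01 expected) and 65 down (1.40), and 339 of the 350 had the same sign.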

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

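The fits without the second Sin3a array, on bright features alone and without both Sin3a-alone arrays, and every alternative to the 7-array fit, were added after seeing the data. Unless said otherwise, the other alternatives were planned. With 2 arrays per group, most counts changed when 1 array was left out. Where a group kept 1 array, that array was assumed to vary like the other groups. Each such omission also took a degree of freedom from the fit, and some counts fell without an array outside the comparison. A changed count therefore does not show that the array left out drove the calls. About 36.1% of probes lay above the floor on each array other than the second Sin3a array (35.7%), so genes of low intensity were not measured. Quantile normalization again and a test of every probe kept each count within 1.5 times of the reported one. Unless a sentence says otherwise, counts are of features that passed the test, the fit had 8 arrays, and the cause was not tested.

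A floor of 32 gave 24 for Nanog against EV, 2 for Sin3a against EV, 127 for Nanog+Sin3a against EV, 2 for Nanog+Sin3a against Nanog, 112 for Nanog+Sin3a against Sin3a, 374 for the Nanog main effect and 4 for the Sin3a main effect. That floor also raised the filter, which then kept only features above 32 in at least 2 arrays. An offset of 16 in place of the floor, with the further shift that brought the lowest value to 1, gave 10 for Nanog against EV and 31 for Nanog+Sin3a against Sin3a. With median centring the counts were 2 for Nanog against EV, 4 for Nanog+Sin3a against EV, 0 for Nanog+Sin3a against Sin3a, 23 for the Nanog main effect and 0 for the Sin3a main effect. Cyclic loess gave 1 for Nanog+Sin3a against Sin3a, 84 for the Nanog main effect and 0 for the Sin3a main effect. No filter, which tests more features, gave 26 for Nanog against EV, 11 for Sin3a against EV, 58 for Nanog+Sin3a against EV, 24 for Nanog+Sin3a against Nanog, 29 for the interaction, 87 for the Nanog main effect and 30 for the Sin3a main effect. The 75th percentile filter, which tests fewer features, gave 36, 3, 159, 2 and 113 for the 5 comparisons between groups in that order, with Nanog+Sin3a against Sin3a last, and 360 and 4 for the Nanog and Sin3a main effects. Without an intensity trend the counts were 7 for Nanog against EV, 6 for Nanog+Sin3a against EV, 4 for Nanog+Sin3a against Sin3a, 64 for the Nanog main effect and 0 for the Sin3a main effect. A minimum log2 change of 0.58 gave 81 for the Nanog main effect.

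With the replicate number as a block the counts were 11 for Nanog+Sin3a against EV, 3 for Nanog+Sin3a against Sin3a, 51 for the Nanog main effect and 0 for the Sin3a main effect, and in 7 arrays 198 for Nanog against EV, 530 for Nanog+Sin3a against EV, 0 for Nanog+Sin3a against Nanog and 50 for Nanog+Sin3a against Sin3a. The block takes a degree of freedom from the fit. The replicate numbers did not pair the arrays, since the differences between replicates correlated across features between groups at -0.0577 to 0.0300.

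On the bright features the counts were 222, 4, 392, 6 and 266 for the 5 comparisons, 1 for the interaction, and 609 and 8 for the Nanog and Sin3a main effects. On these features median centring called 0 or 1 in each of the 8 contrasts, and cyclic loess 10 for Sin3a against EV and 2 for the interaction. The medians came from all probes that passed the main filter, so the bright features were not centred on their own median. For Nanog+Sin3a against Nanog, Krt14 stayed at 1.30 with median centring while its SE went from 0.13 to 0.60. The calls lost with median centring therefore say little about the bright features themselves. Without both Sin3a-alone arrays there were 395 for Nanog against EV, 1009 for Nanog+Sin3a against EV and 6 for Nanog+Sin3a against Nanog. A fit of only the 4 arrays compared gave 413, 2, 1177, 4 and 61 for the 5 comparisons.

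In 7 arrays a floor of 32 gave 566 for Nanog against EV, 4 for Sin3a against EV, 15 for Nanog+Sin3a against Nanog, 436 for Nanog+Sin3a against Sin3a and 2 for the interaction. The offset gave 7 for Sin3a against EV, 24 for Nanog+Sin3a against Nanog, 382 for Nanog+Sin3a against Sin3a and 5 for the interaction, and cyclic loess gave 5 for Nanog+Sin3a against Nanog. No filter gave 46, 271, 114, 16 and 381 for the 5 comparisons and 281 for the interaction, and the 75th percentile filter 822, 8, 1586, 37 and 557, and 4 for the interaction. Without a trend there was 1 for Sin3a against EV and 1 for Nanog+Sin3a against Nanog, and a robust fit gave 1 for Sin3a against EV, 15 for Nanog+Sin3a against Nanog and 1 for the interaction. The bright features of these arrays gave 190, 3, 341, 6 and 82 for the 5 comparisons and 3 for the interaction. Without both Sin3a-alone arrays Nanog+Sin3a against Nanog had 6.

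Leaving out each array in turn from the 8 gave 0 to 350 for Nanog against EV, 0 to 6774 for Sin3a against EV, 0 to 950 for Nanog+Sin3a against EV, 0 to 2 for Nanog+Sin3a against Nanog, 0 to 7019 for Nanog+Sin3a against Sin3a, 0 to 5975 for the interaction, 7 to 6768 for the Nanog main effect and 0 to 6184 for the Sin3a main effect. The values of 6774, 7019, 5975, 6768 and 6184 came without the first Sin3a array, and those of 350, 950 and 2 without the second. From the 7 arrays the ranges were 0 to 95, 0 to 0, 0 to 603, 0 to 0 and 0 to 0 for the 5 comparisons and 0 to 0 for the interaction. The correlation of the Nanog effects ranged from 0.138 to 0.620 and that of the Sin3a effects from 0.0176 to 0.0969. On bright features these were 0.690 and 0.221. Over the 20 features called in either Nanog effect, Nanog itself included, the correlation of the Nanog effects was 0.935. Picking features by a large change in these same effects raises that value.

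Gene lists called were 2 with fry and 3 with no filter for Nanog against EV, 0 with an estimated correlation, 0 with fry and 2 with no filter for Sin3a against EV, 1 and 1 with fry and no filter for Nanog+Sin3a against EV, 1 and 3 for Nanog+Sin3a against Nanog, and 0 with an estimated correlation and 0 with fry for the interaction. Without the second Sin3a array camera called 3 lists for Sin3a against EV, 4 for the interaction and 0 for each of the other 4 comparisons, and all 7 calls were lost with an estimated correlation (adjusted p = 0.352 to 0.517). Without its Nanog member, a setting added after the data were seen, the pluripotency list was called by camera in 7 arrays for Sin3a against EV (adjusted p = 0.0336, and 0.486 with an estimated correlation) and the interaction (0.00281, and 0.352) and lost its fry calls against EV and, in 7 arrays, for the interaction.

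Of the named genes, the directions that turned were Sin3a in Nanog+Sin3a against Sin3a (-0.39), Ndufa9 (-0.13) and Atp2a3 (-0.16) with median centring, Sin3a in the interaction without the second Nanog array (0.12) or the second EV array (0.06), with a range of -0.33 to 0.12 over the arrays left out, and Tpt1 (-2.46 to 0.12), Spink10 (-2.26 to 0.12) and Syne4 (-2.10 to 0.31) in Nanog+Sin3a against Sin3a, whose highest values came without the first Sin3a array. Of 99 values of named genes, 33 lost their call with median centring without a turn of direction, and 5 gained one. Ndufa9 and Atp2a3, which turned, lost their calls too. Lost and gained calls were 22 and 3 with cyclic loess, 32 and 6 without a trend, and 24 and 0 with the replicate block. They were 0 and 22 with a floor of 32, and 18 and 1 with no filter.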

Other observations

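The genes of detoxification described here, the tests of array noise, of other RNA levels, of another group's sample, of Nanog RNA and of shared paralog probes, and the counts on bright features were chosen after the results were seen. These genes were picked by their values and are no tested group. Of 20 measured genes of an antioxidant list, 1 rose and 0 fell with Nanog against EV in 7 arrays and 3 rose and 1 fell with both transgenes, with no call by camera, but that list holds Ephx1, Nqo1 and Akr1b8 and so is not independent of the genes described. Gsta4, an alpha-class glutathione S-transferase, rose by 1.83 with Nanog (adjusted p = 0.0106) and 2.60 with both transgenes (0.00245) on the log2 scale, and Gstm2, of the mu class, by 1.35 (0.0103) and 1.73 (0.00303). Ephx1, the microsomal epoxide hydrolase, rose by 0.81 (0.0457) and 1.35 (0.00758), and Cbr3 by 1.31 (0.00409) and 2.31 (0.000640). Nqo1, a quinone reductase, rose by 0.75 with both transgenes (0.0159) and was at 0.31 with Nanog (0.191). Gsta3 was at 0.92 with Nanog (0.0699) and 0.57 with both transgenes (0.129), while Aldh3a1 fell with Nanog (-0.95, 0.0140) and with both (-0.92, 0.0107). Akr1b8, an aldo-keto reductase, fell with both transgenes (-1.04, 0.00788). The counts of these 7-array comparisons against EV fell without any 1 of the Nanog, Nanog+Sin3a or EV arrays, and each omission also took a degree of freedom. Other probes of Gstm2 gave 1.29 and 0.95 with Nanog, and 1.66 and 0.91 with both transgenes.

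The second Sin3a array departed from the first at 78.8% of probes with a mean log2 value from 5 to 8 and at 0.224% of those at 9 or above. Other RNA levels in this sample were argued against, since over 1338 genes with at least 2 such probes the difference between the Sin3a arrays correlated at -0.0357 (SE 0.0273) between 2 probes of 1 gene, where that between Nanog and EV correlated at 0.539. A sample of another group under this label was argued against too, since its Sin3a probe lay 1.27 (log2) above the highest array without the Sin3a transgene and its Nanog probe was at the floor. Noise of this array under a brightness limit may account for the pattern, but the share of 78.8% is what prompted that explanation and cannot decide for it. Where such noise would have arisen stays open.

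More features passed against EV with both transgenes (950) than with Nanog alone (350) in 7 arrays, a ratio of 2.71, and more Nanog RNA with both transgenes was argued against, since the Nanog probe read 0.676 times its value with Nanog alone. Whether 1 weakly responding array held the Nanog group back stays open. Responses against EV were projected across features on the difference between 1 Nanog+Sin3a array and the first Sin3a array. The second Nanog array showed 0.872 (0.846 to 0.897 over 4 estimates) of the response of the other Nanog+Sin3a array, and the first Nanog array 0.752. Changes that only the Nanog+Sin3a arrays share lower these ratios, so a value under 1 does not show a weaker response to Nanog. The 4 estimates reuse the same arrays, and the counts did not settle the question. In 7 arrays both transgenes gave 380 features against 0 for Nanog without the first Nanog array and 603 against 1 without the second, while on bright features they gave 1.77 times the count of Nanog with all arrays, 539 against 489 without the first and 541 against 92 without the second. Scaling between arrays stays open as well, since the ratio of 2.62 with cyclic loess comes from a rescaling that hardly moved either count (376 and 986) of arrays already quantile-normalised. A higher count of calls is not by itself a larger response. Nanog+Sin3a against Nanog, the direct comparison, called 0 features in 8 arrays and 6 of the 2300 bright features. Of the 350 features called with Nanog, 165 (47.1%) changed more in the same direction with both transgenes. Their choice by the Nanog calls lowers that share. That Sin3a may add to the response of Nanog is a further open hypothesis. The interaction, which tests it directly, called 0 features in limma in 8 arrays (389 at an unadjusted p under 0.05). In 7 arrays it rests on 1 Sin3a array, with a median SE of 0.277 against 0.175 for Nanog against EV. Of the 2300 bright features it called 1, Acta2, which lay below the sum (-1.54), and 0 above the sum. That fit leaves out dimmer features such as Gsta1 and Gsta2, and a feature that did not pass is not shown to be additive. The interaction can therefore not decide for or against this hypothesis.

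Gsta1 and Gsta2 were higher with both transgenes than with Nanog alone. A wider antioxidant response stays open. The 20 measured genes of the antioxidant list had a median change of -0.019. But the list left out genes such as Cbr3 (1.00 on the bright features, where it passed), Gsta4 (0.76) and Gstm2 (0.38, other probes 0.37 and -0.04). Its planned bound could therefore not exclude that explanation. Probes of near-identical paralogs might share their signal, and the smallest change among the Gsta1 and Gsta2 probes was 1.83, so 1 gene that rose cannot be told apart from both, since Gsta2 had 1 probe and nothing measured its specificity. An effect of Sin3a on these genes stays open as a hypothesis.

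The arrays were also split in each of the 34 other ways into groups of the same sizes (35 splits with the real one). For the Nanog main effect the real split gave the most features. In 8 arrays it gave 246 against 1 for the highest other, and in 7 arrays 1480 against 102. Chance is not excluded by this, since 1 in 35 is the smallest share that 35 splits can give. The splits also treat all arrays as separate, while the labels do not say whether arrays of a group came from separate cultures. For the Sin3a main effect the real split gave 1 feature in either fit, and the highest other gave 246 in 8 arrays and 1480 in 7. That other split is the one by the Nanog transgene, a factor of the design that these fits left out, so in 8 arrays, where it was the only other split as large (2 with the real one), the splits do not tell whether chance can be excluded. In 7 arrays 3 splits were as large, the real one and that by Nanog included, and chance cannot be excluded. These fits had no term for the other transgene, so their counts differ from those of the main effects in the report.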
